A study of Mus musculus with 16 samples.

How the data were processed

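The deposited values came from 16 Clariom S arrays, a 1-colour Affymetrix array that measures mouse messenger RNA with 1 summarized value per gene transcript cluster. Per the labels' protocols, 24 C57BL/6 mice of both sexes, aged 7 to 12 weeks, stayed singly in clean air chambers for 40 h at an airflow of 3.1 L per min. From 26 h on, 12 of them received the odorant mixture for 10 s every 20 min and the others filtered air as vehicle. The mixture held undecanal, a fatty aldehyde, and bourgeonal, an aromatic aldehyde with a floral smell. The mice carried S100a5-tauGFP, a reporter allele in which the activity-dependent gene S100a5 of olfactory sensory neurons (OSNs) drives a fluorescent protein. Olfactory mucosa was dissociated, and each of 8 pools of 3 mice was sorted by fluorescence into 2 fractions. Biotinylated cRNA was prepared from 50 to 100 ng of total RNA, per the labels' protocols.

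The deposited values were used as log2 array signals, a unit read from their range, 1.77 to 19.3 over the 16 arrays, and their like quartiles. Affymetrix Expression Console made them, per the submitters' processing notes, with no version given. The background correction, normalization and summarization were not given in the sources used here, so the scale between arrays is as deposited. The value table held 28846 entries per array. Of these, 19572 carried 1 gene symbol and were tested, none carried several, and 2634 transcript clusters were unnamed here. The remainder were 5222 negative controls, 1324 positive controls, 23 background probe sets graded by GC content and 71 other controls. All 19572 tested features matched an Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table served for names, synonyms and the order of neighbouring genes. No genome build was given for the values, so no coordinates are reported. The features covered 19505 genes, of which 55 had more than 1 feature, and included 1081 intact olfactory receptor genes. The array names receptors by their older Olfr symbols.

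Samples were grouped by title into odor or vehicle and GFP+ or GFP−, with 4 arrays in each of 4 groups. Each sample's cell type characteristic states the opposite GFP status to its title, on all 16 arrays. The titles were kept, and the fractions are called "titled GFP−" and "titled GFP+" throughout. Fraction differences are given as titled GFP− minus titled GFP+. This is the reverse of the order written into the design before the data were examined. The groups, comparisons, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Each replicate was a pool of different mice, so the spread between arrays of a group holds differences between pools as well as technical error.

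A limma cell-means model over the 4 groups was fitted to the log2 values (limma 3.58.1, R 4.3.3), with moderated two-sided tests and Benjamini-Hochberg adjustment over the 19572 features at 0.05. The 5 comparisons were the fraction difference in vehicle pools, the fraction difference in odor pools, their difference (the interaction), and odor against vehicle within each titled fraction. SE values come from that model, and ± SD from the 4 arrays of a group. Exact permutation tests of single values were two-sided, and with 4 arrays against 4 their smallest p is 0.0286. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 24 lists per comparison, with camera at an estimated correlation and fry beside it. Camera compares a list with all other features, while fry asks whether a list's genes move one way on balance. A list needed 3 measured members.

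The lists held olfactory receptors, trace amine-associated receptors, activity-dependent OSN genes, immediate-early genes, axon sorting molecules, and markers of mature OSNs, immature OSNs, basal and progenitor cells and cycling cells. Others held markers of sustentacular cells, respiratory ciliated cells, microvillar cells and ionocytes, Bowman glands, ensheathing glia, neutrophils, other leukocytes, erythroid cells, endothelial and mesenchymal cells, guanylyl cyclase D neurons and vomeronasal neurons. The last held heat shock genes, unfolded protein response genes, cytosolic ribosomal proteins and oxidative phosphorylation genes. A pair of preset receptors, Olfr16 and Olfr2, was chosen for known responses to aldehydes and tested with adjustment over these 2 alone. Few genes stood in more than 1 list: 3 were shared by the immature OSN and unfolded protein response lists and 1 each by 3 other pairs of lists.

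For each fraction comparison the rule named the 5 highest and 5 lowest receptors (olfactory or trace amine) and the 10 highest and 10 lowest other genes among those past the threshold. For the other comparisons it named up to 12 receptors at the high and 6 at the low end and 8 other genes at each end. Where fewer than 5 of a kind passed, the 5 with the smallest p were named as not passing. S100a5, Omp, Gap43, Kirrel2, Pcp4l1, Fos, Egr1, Olfr16 and Olfr2 were always named, with up to 4 members of each described list by smallest p.

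Background was taken on each array as the 95th percentile of the graded background probe sets. Where every array of the dimmer group lay at or under it, the fold is given as "at least", from the brighter group's mean log2 value against the dimmer group's mean after raising its arrays to their background. The same was done, as a choice made after the data were seen, where 1 or 2 of the 4 dimmer arrays lay above it, and their number is given. Where both groups lay under it on all arrays, no fold is given. A list's bounded median takes such members at their bound, and at 0 where both groups lay under it.

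The replicate numbers were taken to pair the samples. Both fractions of a pool came from the same mice, and their deviations from the group means correlated at 0.0957 to 0.337 across features. Odor and vehicle pools of the same number correlated at 0.147 to 0.547, all over the minimum of 0.1, and 15 of 16 arrays correlated best with an array of their own number. The series design says that both treatments ran simultaneously. That odor and vehicle pools of the same number belong together was inferred from this and from the correlations. Alternative fits therefore took the pool as a block for fraction comparisons and the interaction, and the number as a block for odor against vehicle. Replicate arrays of a group correlated at 0.979 or more, and no 2 arrays of the 16 held identical values.

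Further alternatives were renewed quantile normalization, centring on the median of all tested features or of the receptors, removal of the dimmest 25% of features, an intensity trend with robust estimation, array weights, only the groups compared, the pool as a random block, a threshold of 0.1, a log2 minimum of 1, and leaving out each pool. Others were added after the data were seen: the negative-control median as a covariate, list tests without each pool, bounded medians of lists, the number as a block over all arrays, adjustment over the receptor list alone in comparisons for which it was not planned, and receptors split by MOR family, an older sequence-based naming of mouse receptors, into class I (families up to 42) and class II (families from 101). The class I list by newer receptor symbols was not run, since the names used here lack them.

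The pipeline was tested on simulated data with 50 changed features of each size among 19572. At a log2 change of 1 it recovered 64% in the vehicle fraction comparison, 62% in the odor fraction comparison, 40% in the interaction, 66% for odor in the titled GFP− fraction and 80% in the titled GFP+ fraction. At a log2 change of 2 these shares were 92%, 100%, 90%, 94% and 94%. False calls made up 3.52%, 2.90%, 4.88%, 6.08% and 2.05% of calls. The noise was drawn independently for each feature and array, without correlation between pools or genes and without deviating arrays. These shares may therefore not hold for the real arrays. The number of arrays limits the precision of each value. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.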

Results

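Gene expression was measured in 16 sorted fractions of mouse olfactory mucosa, with 4 arrays in each of 4 groups: odor titled GFP+, odor titled GFP−, vehicle titled GFP+ and vehicle titled GFP−. Each array held RNA from a pool of 3 mice that carried the S100a5-tauGFP reporter, and both fractions of a pool came from the same animals. The mice had smelled either a mixture of undecanal and bourgeonal or filtered air. Replicate arrays of a group correlated at 0.979 to 0.995 across the 19572 tested features. The first principal component held 71.1% of the variance and the second 6.34%. Array medians of the tested features averaged 6.81 in both titled GFP− groups, against 7.11 in the odor and 7.21 in the vehicle arrays titled GFP+ (log2 signal, n = 4 each).

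The gene that drives the reporter was examined first. S100a5, a calcium-binding protein gene switched on by activity in olfactory sensory neurons (OSNs), was higher in the fraction titled GFP− in all 8 pools, which goes against the titles. The differences were 2.43, 0.71, 1.08 and 1.03 log2 units in the odor pools and 0.94, 0.85, 1.13 and 1.07 in the vehicle pools. The fitted differences were 1.31 ± 0.20 (SE, adjusted p = 1.6e-04) with odor and 1.00 ± 0.20 (adjusted p = 0.0019) with vehicle. The cell type characteristics of the samples, which oppose the titles on every array, name this same fraction as the fluorescent one. S100a5 and these characteristics thus argue that the cells titled GFP− are the fluorescent ones. Leukocyte markers, described below, argue the same way, since the reporter is driven by a gene of OSNs. All 11 neutrophil and all 15 other leukocyte markers were lower in the titled GFP− fraction in both treatments. All directions here still follow the titles. If the characteristics are right, each fraction difference reads as fluorescent minus non-fluorescent cells. Centring the arrays on their receptor median left 0.73 in vehicle pools, with an adjusted p of 0.109. That median was itself higher in titled GFP− than in titled GFP+ arrays (means of 9.13 against 8.86 in vehicle and 9.06 against 8.60 in odor pools). This centring therefore lowers every difference of titled GFP− minus titled GFP+.

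**Figure D1:**
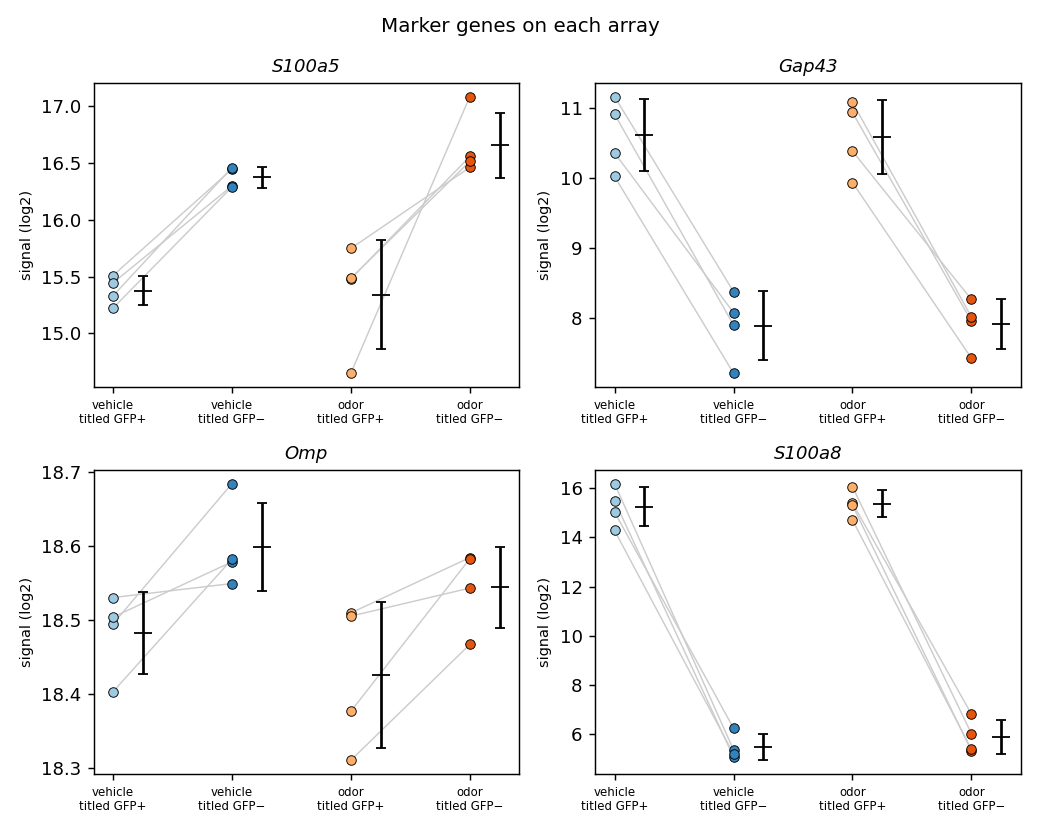
Log2 signals of S100a5, Gap43, Omp and S100a8 on each array by group, with lines joining the fractions of a pool and bars giving the mean ± SD of 4 arrays. S100a5 was higher in the titled GFP− fraction of every pool (0.71 to 2.43), Gap43 and S100a8 lower in every pool, and Omp differed by 0.12 on average in each treatment.

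In vehicle pools, which had smelled filtered air only, the fractions differed in their receptors, their OSN maturity markers and their markers of other cells. The titled GFP− fraction had higher signals of 6 of 7 activity-dependent OSN genes and of 360 olfactory receptors. The titled GFP+ fraction had higher signals of 222 other receptors, of 6 of 15 immature OSN markers and of all cell cycle, microvillar and leukocyte genes listed. The largest differences were in neutrophil genes. Lcn2 (lipocalin 2) was at least 1270-fold, Ngp (neutrophilic granule protein) at least 1245-fold and S100a8 at least 268-fold higher in the titled GFP+ fraction (adjusted p of 3.1e-12, 7.4e-11 and 9.3e-11).

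In total 3302 of 19572 features passed, 1380 higher and 1922 lower in the titled GFP− fraction. The split depended on the scaling: it was 2643 and 1863 after renewed quantile normalization, 12456 and 1529 after centring on the median of tested features, and 344 and 1806 after centring on the receptor median. The median over all features moved from 0.13 as deposited to 0.54 and −0.14 under these centrings, and small differences are relative to that shift. Without vehicle replicate 1, 2138 features passed (681 higher, 1457 lower).

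Olfactory receptors differed more often than other genes, with 65.8% at an unadjusted p under 0.05 against 28.5% of the rest. The sets were not matched for detection. In vehicle arrays titled GFP− and GFP+, medians averaged 9.13 and 8.86 for receptors. Those of all tested features averaged 6.81 and 7.21, near the background of 6.87 to 7.41. Of 1081 receptors, 582 passed over all features and 673 adjusted over the list alone. Among the highest in the titled GFP− fraction were Olfr1093, Olfr372, Olfr481 and Olfr613, at least 17.0-, 14-, 12.2- and 4.90-fold higher (adjusted p up to 7.0e-07). Olfr110, above background on 3 of 4 dimmer arrays, differed by 5.51 ± 0.23 log2 units (adjusted p = 7.8e-11). At the other end, Olfr1507, Olfr99, Olfr1384, Olfr794 and Olfr390 were at least 134-, 98.2-, 73.7-, 60.6- and 55.1-fold higher in the titled GFP+ fraction (adjusted p up to 1.3e-08). As a group the receptors had a median difference of 0.42, or a bounded median of 0.11, in which members below background on all arrays of a group stand at the bound that the background allows. Camera did not call the list (adjusted p = 0.235, and adjusted p = 0.733 with an estimated correlation). Split by MOR family after the data were seen, class I receptors had 24 higher and 17 lower of 120, and class II receptors 331 and 198 of 941.

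Olfr16, a preset receptor for aldehydes, was lower in the titled GFP− fraction of vehicle pools at −2.28 ± 0.58 (adjusted p = 0.012). It did not pass without vehicle replicate 1, 2 or 4 (−2.29, −1.91 and −1.98, adjusted p = 0.0548, 0.0875 and 0.0810). Olfr2, the other preset aldehyde receptor, differed by −0.25 ± 0.44 (adjusted p = 0.73). Trace amine-associated receptors, which detect amines, had 4 of 14 higher and 4 lower, or 7 and 4 adjusted over the list alone, with no common direction by camera (adjusted p = 0.838). Taar4 differed by 2.19 ± 0.57, Taar7f by −1.38 ± 0.35 and Taar7d by −1.02 ± 0.27 (adjusted p = 0.013, 0.011 and 0.015), and Taar8a was below background in both groups. None of these 4 held in every fit that left out 1 vehicle pool: Taar4 was lost without replicate 1, 2 or 3, Taar7d and Taar7f without 2 or 3, and Taar8a without 1, at adjusted p up to 0.109.

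Activity-dependent OSN genes were higher in the titled GFP− fraction in 6 of 7, with a median of 1.18 (camera adjusted p = 2.6e-04, and adjusted p = 0.0303 with an estimated correlation, or 0.0546 without vehicle replicate 4). Lrrc3b was higher by 1.88 ± 0.38, Pcp4l1 by 1.67 ± 0.22, Plcxd3 by 1.23 ± 0.17 and Kirrel2, an adhesion molecule that sorts OSN axons, by 1.18 ± 0.26 (adjusted p of 0.0038 or less). Omp, the olfactory marker protein of mature OSNs, differed by 0.12 ± 0.10 (adjusted p = 0.46) near the top of the signal scale. It passed at 0.52 (adjusted p = 0.0011) with arrays centred on the median of tested features. Of 18 mature OSN markers 4 passed upward and 5 adjusted over the list alone, with a median of 0.25 that turned to −0.02 with arrays centred on the receptor median. Camera called the list (adjusted p = 0.0036), but adjusted p = 0.185 with an estimated correlation and adjusted p = 0.160 with arrays centred on the receptor median. Pde1c, a phosphodiesterase of the odorant response, led at 0.57 ± 0.10 (adjusted p = 7.2e-04), and Ano2, Pde4a and Slc17a6 stood at 0.39, 0.40 and 0.34. Ano2 was lost without vehicle replicate 1, 2 or 3. Pde4a was lost without any 1 vehicle pool or odor replicate 3 or 4, and Slc17a6 without any 1 vehicle pool or odor replicate 2, 3 or 4 (adjusted p up to 0.188). Without 1 pool the differences ranged from 0.38 to 0.43 (Ano2), 0.34 to 0.45 (Pde4a) and 0.31 to 0.39 (Slc17a6). Leaving out an odor pool leaves a difference in vehicle pools unchanged and alters only its estimated spread and adjusted p. With the pool as a block Pde4a and Slc17a6 had adjusted p of 0.0519 and 0.0715.

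Immature OSN markers were lower in the titled GFP− fraction in 6 of 15 (camera adjusted p = 4.1e-05, and adjusted p = 0.0442 with an estimated correlation, or up to 0.0700 without any 1 pool other than vehicle replicate 1). Their median of −0.23 (bounded −0.16, and −0.37 without vehicle replicate 2) turned to 0.17 with arrays centred on the median of tested features. Gap43, a growth cone gene of immature OSNs, differed by −2.72 ± 0.31 (adjusted p = 6.3e-06), Dpysl3 by −4.12 ± 0.23 and Stmn1 by −2.31 ± 0.21 (adjusted p = 2.1e-09 and 6.7e-07). Gng8, a G protein subunit of immature OSNs, was at least 13.6-fold higher in the titled GFP+ fraction (adjusted p = 3.7e-10). Immediate-early genes, the transient first responders to stimulation in many cell types, were lower in 17 of 22, or 19 adjusted over the list alone, with a median of −2.42 (bounded −1.36, camera adjusted p = 2.9e-16, and adjusted p = 0.0277 with an estimated correlation, or 0.0510 without vehicle replicate 4). Fos and Egr1 differed by −4.29 ± 0.58 and −4.63 ± 0.45 (adjusted p = 4.5e-05 and 1.2e-06), and Egr2 was at least 50.9-fold higher in the titled GFP+ fraction. These genes moved with the leukocyte markers below, and leukocytes transcribe them too. Whether leukocytes account for the difference was not tested. Axon sorting molecules had 3 of 13 higher and 1 lower (5 and 1 adjusted over the list alone). Camera did not call the list (adjusted p = 0.487), while fry called it higher (adjusted p = 0.0087, and 0.0163 with the pool as a block). Epha5 differed by 0.95 ± 0.21 and Pcdh10 by 1.04 ± 0.31, and Sema3a was at least 1.38-fold higher in the titled GFP+ fraction (adjusted p = 0.0035, 0.030 and 0.024). Leaving out vehicle replicate 1, 2 or 3 ended the call of Pcdh10, and leaving out any vehicle replicate that of Sema3a (adjusted p up to 0.141).

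Markers of most other cell types were lower in the titled GFP− fraction. All 11 neutrophil markers were lower (bounded median −6.72, with all 11 below background in the titled GFP− fraction, camera adjusted p = 9.7e-29, and adjusted p = 0.0061 with an estimated correlation), as were all 15 other leukocyte markers (bounded median −1.995, camera adjusted p = 1.8e-22, and adjusted p = 0.0197 with an estimated correlation). Fcer1g and H2-Aa were at least 43.1- and 13.4-fold higher in the titled GFP+ fraction. Lyz2 and Laptm5, each above background on 1 of 4 dimmer arrays, were at least 240- and 55.6-fold higher there. All 8 microvillar cell and ionocyte markers were lower (bounded median −0.998, camera adjusted p = 7.2e-13, and adjusted p = 1.6e-04 with an estimated correlation), with Foxi1 and Trpm5 at least 8.20- and 5.98-fold higher in the titled GFP+ fraction. All 15 cell cycle genes were lower (bounded median −0.54, camera adjusted p = 7.0e-15, but adjusted p = 0.0603 with an estimated correlation), and Mki67, Rrm2 and Plk1 were at least 20.5-, 4.53- and 3.58-fold higher in the titled GFP+ fraction.

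Basal and progenitor markers were lower in 4 of 10 (bounded median 0.00, with 7 of 10 below background in both groups, camera adjusted p = 0.0018, and adjusted p = 0.0372 with an estimated correlation), or 1 higher and 5 lower adjusted over the list alone. Kit was at least 3.33-fold higher in the titled GFP+ fraction, while Hes6 and Neurog1 lay below background in both groups, and Neurog1 was lost without vehicle replicate 1 or 3 (adjusted p = 0.0623 and 0.0992). Sustentacular markers were lower in 5 of 9, or 6 adjusted over the list alone (median −1.83, bounded −1.63, camera adjusted p = 7.1e-06, but adjusted p = 0.125 with an estimated correlation). Krt18 and Krt8, keratins of supporting cells, were at least 6.35- and 2.48-fold higher in the titled GFP+ fraction, and Cyp1a2 and Sult1c1 differed by −1.83 ± 0.41 and −2.73 ± 0.62. All 3 measured erythroid markers were lower (bounded median −1.72, camera adjusted p = 0.0014, but adjusted p = 0.125 with an estimated correlation), with Slc4a1, the band 3 anion exchanger, at −3.07 ± 0.48 (adjusted p = 1.9e-04). Epb42, above background on 1 of 8 arrays, was lost without vehicle replicate 1 or 3 (adjusted p = 0.0915 and 0.0529). Markers of guanylyl cyclase D neurons were lower in 5 of 9, or 7 adjusted over the list alone (bounded median −0.02, camera adjusted p = 1.1e-05, and adjusted p = 0.0372 with an estimated correlation). The lead members Ms4a6c and Ms4a4c are also genes of macrophages and other leukocytes and were at least 3.65- and 5.84-fold higher in the titled GFP+ fraction, as was Pde2a at 7.96-fold. Vomeronasal markers were lower in 2 of 3 (bounded median −0.05, camera adjusted p = 0.0014, and adjusted p = 0.0277 with an estimated correlation). They were led by Gnai2, a G protein subunit also abundant in leukocytes, at least 47.4-fold higher in the titled GFP+ fraction (above background on 1 of 4 dimmer arrays), with Meis2 below background in both groups. With an estimated correlation these calls were lost without vehicle replicate 4 for basal, guanylyl cyclase D and vomeronasal markers, without any 1 odor pool for basal markers and without odor replicate 1 or 2 for guanylyl cyclase D neurons (adjusted p up to 0.0684).

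Bowman gland markers had 1 of 9 lower, Sox9 at least 7.95-fold, with a median of −0.24 that turned to 0.04 after quantile normalization and 0.17 after centring on the median of tested features. The bounded median was 0.00. Camera called them lower (adjusted p = 0.031, but adjusted p = 0.214 with an estimated correlation), with no call on arrays centred on the receptor median (0.129) or without vehicle replicate 1 (−0.20, 0.0853) or 4 (−0.03, 0.125), and a median of −0.42 without replicate 3. Of 5 ensheathing glia markers only Apoe, also a macrophage gene, passed (−3.33 ± 0.43, adjusted p = 2.9e-05). Camera did not call the list (adjusted p = 0.111), while fry called it lower (adjusted p = 0.0019, and 0.0119 with the pool as a block). Respiratory ciliated cell markers had 2 of 11 higher, Ccdc113 and Dnah5, and the list passed upward (median 0.42, bounded 0.18, camera adjusted p = 0.031, but adjusted p = 0.213 with an estimated correlation, and adjusted p = 0.0591 without vehicle replicate 1). Ccdc113 was above background on 2 of 4 arrays of the brighter group and at least 1.13-fold higher, and Dnah5 on none. No member passed among 9 heat shock genes, 12 unfolded protein response genes or 10 endothelial and mesenchymal markers, and camera called none of these lists (adjusted p = 0.219, 0.538 and 0.736). With the pool as a block the heat shock list was called lower (camera adjusted p = 0.0213), but adjusted p = 0.576 with an estimated correlation in the unblocked fit. Fry called this list with the block (adjusted p = 0.0010) and not without it (adjusted p = 0.352). The unfolded protein response list had a median of 0.06, a mean of −0.02 and a camera direction downward.

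Cytosolic ribosomal protein genes had 17 of 66 lower and 1 higher in the titled GFP− fraction, or 27 and 1 adjusted over the list alone (median −0.43, camera adjusted p = 2.2e-09, but adjusted p = 0.312 with an estimated correlation). Rplp0, a stalk protein of the large ribosomal subunit, differed by −1.71 ± 0.24, and Rps26, Rpl32l and Rps20 by −0.87, −0.81 and −0.80. Oxidative phosphorylation genes had 7 of 89 higher and 1 lower, and 0 adjusted over the list alone by limma (median 0.29, camera adjusted p = 0.0018, but adjusted p = 0.623 with an estimated correlation). Cox7a1 and Ndufv1 differed by 0.77 ± 0.18 and 0.37 ± 0.11 (adjusted p = 0.0068 and 0.033). The first was lost without vehicle replicate 1 (0.71, adjusted p = 0.0544), the second without any of vehicle replicates 1 to 3 or odor replicates 2 and 3 (adjusted p up to 0.167). Other genes higher in the titled GFP− fraction were led by Fxyd2, a regulator of the sodium pump, at 3.55 ± 0.37 (adjusted p = 2.9e-06), followed by the pseudogene Olfr911-ps1 (2.00), Caly (1.70), Ptprn (1.68), Avp (at least 2.33-fold) and Cidea (1.52). Rxfp1 and Gm5901 passed while below background on all arrays. The dimmer group was above background on 3 of 4 arrays for Olfr911-ps1, Caly, Ptprn, Cyp1a2, Sult1c1 and Cox7a1, and on 1 for Avp and Sema3a. With arrays centred on the receptor median the calls of Kirrel2, Epha5, Pcdh10, Pde1c, Ano2, Pde4a, Slc17a6, Cox7a1, Ndufv1 and Ccdc113 were lost (adjusted p of 0.0783 to 0.967). That centring takes the higher receptor level of titled GFP− arrays out of each difference.

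**Figure D2:**
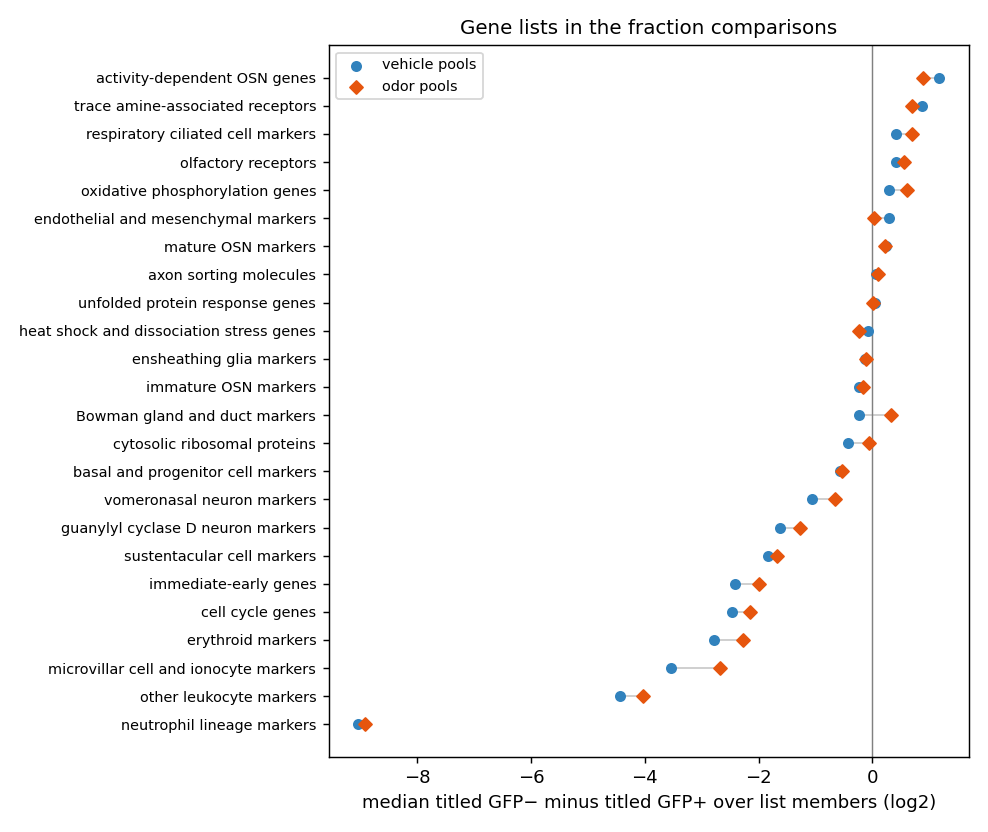
Median titled GFP− minus titled GFP+ difference (log2) over the members of each gene list as fitted in vehicle pools (circles) and odor pools (diamonds), which for neutrophil markers is no measured difference, since nearly all members lay below background in the titled GFP− fraction (bounded medians −6.72 and −6.34). The same limit holds in part for other lists. In vehicle pools, other leukocyte, microvillar and cell cycle markers had bounded medians of −1.995, −0.998 and −0.54, against −4.44, −3.54 and −2.47 as plotted. Guanylyl cyclase D and vomeronasal markers had −0.02 and −0.05, against −1.63 and −1.07. Activity-dependent OSN genes lay highest (1.18 and 0.90), while the medians of mature and immature OSN, Bowman gland, ensheathing glia, axon sorting, heat shock and unfolded protein response lists, and in odor pools of ribosomal and endothelial lists, change sign under another scaling.

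In odor pools, exposed to undecanal and bourgeonal, the fractions again differed in receptors, OSN genes and markers of other cells. The titled GFP− fraction had higher signals of 406 olfactory receptors, of 45 of 89 oxidative phosphorylation genes and of 6 of 7 activity-dependent OSN genes. The titled GFP+ fraction had higher signals of 204 receptors, of 6 of 15 immature OSN markers, of 14 of 15 cell cycle genes and of all leukocyte and microvillar markers listed. Lcn2 was at least 1276-fold, Retnlg at least 445-fold and S100a8 at least 279-fold higher in the titled GFP+ fraction (adjusted p up to 1.4e-10). In total 4338 features passed, 2385 higher and 1953 lower in the titled GFP− fraction. The split was 2930 and 1956 after quantile normalization, 9658 and 1534 after centring on the median of tested features, and 343 and 2433 after centring on the receptor median. The median over all features was 0.14, 0.44 and −0.32 as deposited and under the last pair. Without odor replicate 1, 2689 features passed (1238 higher, 1451 lower).

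Receptors stood out again, with 610 of 1081 passing, 697 adjusted over the list alone, and 67.7% at an unadjusted p under 0.05 against 33.5% of other genes. As before, the sets were not matched for detection. Olfr372 and Olfr1093 were each at least 12.2-fold, Olfr481 at least 8.63-fold and Olfr613 at least 4.34-fold higher in the titled GFP− fraction (adjusted p up to 7.7e-07), and Olfr110, above background on 2 of 4 dimmer arrays, at least 39.5-fold. Olfr1507, Olfr99 and Olfr794 were at least 122-, 72.4- and 55.8-fold higher in the titled GFP+ fraction, and Olfr1297 and Olfr1213, above background on 1 of 4 dimmer arrays, at least 154- and 50.5-fold. The receptor list had a median of 0.57 (bounded 0.21) and did not pass camera (adjusted p = 0.059, and adjusted p = 0.696 with an estimated correlation). Fry called it higher (adjusted p = 0.0363, and 0.0030 with the pool as a block). Camera called it upward with the pool as a block (0.0148) and without odor replicate 2 (0.0211) or vehicle replicate 1 (0.0438). In the fits without these pools it had adjusted p = 0.606 and 0.672 with an estimated correlation. Class I receptors had 32 higher and 13 lower of 120, and class II receptors 368 and 186 of 941. Olfr16 differed by 1.21 ± 0.58 and did not pass (adjusted p = 0.152). It was 0.69 without odor replicate 1 and 0.73 without replicate 2. It passed without odor replicate 4 (2.09, adjusted p = 0.0125) and with arrays centred on the median of tested features (1.51, adjusted p = 0.0387). Olfr2 differed by −0.38 ± 0.44 (adjusted p = 0.57).

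Trace amine-associated receptors had 4 of 14 higher and 1 lower, with no common direction (camera adjusted p = 0.806). Taar4 differed by 2.74 ± 0.57 (adjusted p = 0.0024). Taar9, Taar7e and Taar7d passed at 2.39, 1.16 and −0.90, and were lost without odor replicate 1, 2 or 4 (Taar9, Taar7d) or without any odor pool or any of vehicle replicates 2 to 4 (Taar7e), at adjusted p up to 0.125. Axon sorting molecules had 3 of 13 higher and 1 lower without a common direction (camera adjusted p = 0.922), among them Pcdh10 at 1.09 ± 0.31, Epha5 at 0.72 ± 0.21 and Sema3a, at least 1.31-fold higher in the titled GFP+ fraction (adjusted p = 0.019, 0.019 and 0.022). Pcdh10 was lost without odor replicate 2, 3 or 4, Epha5 without 2 or 3, and Sema3a without 1, 3 or 4 (adjusted p up to 0.0998).

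Activity-dependent OSN genes were higher in 6 of 7 (median 0.90, camera adjusted p = 0.0022, but adjusted p = 0.0505 with an estimated correlation, or 0.0452 without odor replicate 1 and 0.0483 without vehicle replicate 2). Pcp4l1 was higher by 1.69 ± 0.22, Lrrc3b by 1.52 ± 0.38, Kirrel2 by 0.90 ± 0.26 and Plcxd3 by 0.87 ± 0.17 (adjusted p of 0.020 or less), and Kirrel2 was lost without odor replicate 1, 3 or 4 (adjusted p up to 0.0714). Mature OSN markers had 5 of 18 higher, 6 adjusted over the list alone (median 0.23, −0.24 with arrays centred on the receptor median, camera adjusted p = 0.0131, but adjusted p = 0.252 with an estimated correlation and adjusted p = 0.550 with arrays centred on the receptor median). Pde1c was higher by 0.71 ± 0.10 (adjusted p = 8.9e-05), and Ano2, Slc17a6 and Adcy3 by 0.41, 0.40 and 0.30. Ano2 was lost without odor replicate 3, Slc17a6 without 1 or 2 and Adcy3 without any 1 of the 8 pools (adjusted p up to 0.157), and Adcy3 also with the pool as a block (adjusted p = 0.067). Without 1 pool the differences ranged from 0.39 to 0.44, 0.31 to 0.46 and 0.25 to 0.34. Leaving out a vehicle pool leaves a difference in odor pools unchanged and alters only its estimated spread and adjusted p. Omp differed by 0.12 ± 0.10 (adjusted p = 0.42), and by 0.42 with a call (adjusted p = 0.0045) after centring on the median of tested features. Immature OSN markers were lower in 6 of 15 (median −0.16, −0.10 without odor replicate 4, 0.14 with arrays centred on the median of tested features, camera adjusted p = 6.8e-05, but adjusted p = 0.0505 with an estimated correlation, or 0.0452 without odor replicate 1), with Gap43 at −2.67 ± 0.31 and Dpysl3 at −3.85 ± 0.23. Gng8 was at least 10.2-fold higher in the titled GFP+ fraction. Immediate-early genes were lower in 16 of 22, or 18 adjusted over the list alone (median −1.99, bounded −1.13, camera adjusted p = 3.5e-15, and adjusted p = 0.0345 with an estimated correlation, or up to 0.0687 without odor replicate 2 or 4 or vehicle replicate 3 or 4), with Fos at −4.40 ± 0.58 and Egr1 at −5.26 ± 0.45.

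Among other cells, all 11 neutrophil markers (bounded median −6.34), all 15 other leukocyte markers (−1.85) and all 8 microvillar and ionocyte markers (−1.07) were lower in the titled GFP− fraction, with camera adjusted p of 2.7e-27, 4.7e-20 and 3.8e-11, and adjusted p = 0.0076, 0.0292 and 3.5e-04 with an estimated correlation. Cell cycle genes were lower in 14 of 15, and in 15 adjusted over the list alone (bounded median −0.54, camera adjusted p = 1.3e-12, but adjusted p = 0.0894 with an estimated correlation). Basal markers were lower in 4 of 10 (bounded median 0.00, camera adjusted p = 3.0e-04, and adjusted p = 0.0296 with an estimated correlation), with Sox2, Hes6 and Neurog1 below background in both groups. Sustentacular markers were lower in 6 of 9, or 7 adjusted over the list alone (camera adjusted p = 2.0e-05, but adjusted p = 0.153 with an estimated correlation), and all 3 erythroid markers were (camera adjusted p = 0.0058, but adjusted p = 0.167 with an estimated correlation). Krt18 was at least 5.17-fold and Alas2, the heme synthesis enzyme of red cells, at least 2.62-fold higher in the titled GFP+ fraction, and Alas2 was lost without odor replicate 1 (−1.97, adjusted p = 0.0557). Epb42, above background on 1 of 8 arrays, was lost without any 1 odor pool (adjusted p of 0.0551 to 0.160). Markers of guanylyl cyclase D neurons were lower in 6 of 9 and of vomeronasal neurons in 2 of 3 (camera adjusted p = 2.0e-05 and 0.0088, and adjusted p = 0.0499 with an estimated correlation for each), again with Ms4a6c and Gnai2 (at least 44.6-fold, above background on 2 of 4 dimmer arrays) in the lead. Meis2, the other vomeronasal marker called, lay below background in both groups and was lost without odor replicate 2, 3 or 4 or vehicle replicate 3 (adjusted p up to 0.145). With an estimated correlation the calls of other leukocyte markers were lost without odor replicate 2 or vehicle replicate 4, of basal markers without odor replicate 2, 3 or 4 or vehicle replicate 3 or 4, and of guanylyl cyclase D neurons without odor replicate 1, 2 or 3 or vehicle replicate 3 or 4. Those of vomeronasal neurons were lost without odor replicate 2, 3 or 4 or vehicle replicate 1, 3 or 4 (adjusted p up to 0.0691 over these 4 lists).

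Bowman gland markers had 1 of 9 lower, Sox9 at least 9.73-fold, with a median of 0.33 (−0.14 with arrays centred on the receptor median), a mean of −0.32 and no call (camera adjusted p = 0.217). Ensheathing glia markers had 2 of 5 lower, Apoe at −2.76 ± 0.43 and Sox10. The latter lay below background in both groups and was lost without odor replicate 1, 2 or 3 or vehicle replicate 3 (adjusted p up to 0.197). Camera did not call the list (adjusted p = 0.0787), except without odor replicate 1 (−0.34, adjusted p = 0.0284, but adjusted p = 0.0907 with an estimated correlation). Fry called it lower (adjusted p = 0.0018, and 0.0122 with the pool as a block). Ciliated cell markers were higher in 4 of 11 (median 0.70, bounded 0.25, camera adjusted p = 0.0131, but adjusted p = 0.159 with an estimated correlation), with Rsph1 at 1.06 ± 0.22, Dynlrb2 at 0.83 ± 0.17 and Tekt1 at 0.83 ± 0.18. Dynlrb2 was 0.55 without odor replicate 1. Oxidative phosphorylation genes had 45 of 89 higher and 1 lower, or 59 and 2 adjusted over the list alone (median 0.61, and 0.31 without odor replicate 1, camera adjusted p = 3.6e-09, but adjusted p = 0.358 with an estimated correlation). Ndufb7 and Ndufb6, subunits of complex I, were higher by 1.01 ± 0.22 and 0.88 ± 0.19, and Ndufaf5 and Ndufaf1, assembly factors of that complex, by 0.96 ± 0.21 and 0.94 ± 0.20. Without odor replicate 1 Ndufb7, Ndufb6 and Ndufaf5 were 0.65, 0.56 and 0.62 and still passed. Ribosomal protein genes had 3 of 66 lower and 2 higher (2 and 2 adjusted over the list alone), with a median of −0.07 that turned to 0.23 with arrays centred on the median of tested features. Camera did not call them (adjusted p = 0.0545, and adjusted p = 0.767 with an estimated correlation). It called them lower with the pool as a block (0.0431) and without odor replicate 1 (−0.31, 8.9e-09, but adjusted p = 0.261 with an estimated correlation in that fit). Rplp0 differed by −1.30 ± 0.24. The pair that was higher, Rps27l and Rps19bp1 (0.80 and 0.73), are a paralog of a ribosomal protein and a binding partner of one. Heat shock, unfolded protein response and endothelial lists had 0 members past by limma and no call by camera (adjusted p = 0.414, 0.615 and 0.559). The last pair had medians of 0.01 and 0.03, means of −0.02 and −0.06 and camera directions downward. Fry called the heat shock list with the pool as a block (adjusted p = 0.0028) and not without it (adjusted p = 0.765).

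Fxyd2 again led the other genes higher in the titled GFP− fraction at 3.46 ± 0.37, followed by Olfr911-ps1 (at least 4.17-fold), Caly (at least 2.93-fold), Rfx4 (1.53), Avp (at least 1.97-fold) and Kcng1 (1.45), with Cntnap5b and Akap3 below background in both groups. The dimmer group was above background on 3 of 4 arrays for Fxyd2, Egr1, Taar4, Taar7e and Rps19bp1, on 2 for Avp and Sema3a, and on 1 for Olfr911-ps1 and Caly. With arrays centred on the receptor median the calls of Lrrc3b, Kcng1, Kirrel2, Taar7e, Plcxd3, Epha5, Pcdh10, Pde1c, Dynlrb2, Rsph1, Tekt1, Rps19bp1, Rps27l, Ndufb7, Ndufb6, Ndufaf5 and Ndufaf1 were lost (adjusted p of 0.128 to 0.563), and Ano2, Slc17a6 and Adcy3 changed sign without a call. Here too the centring takes the higher receptor level of titled GFP− arrays out of each difference.

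The fraction differences of vehicle and odor pools, which share no array, were alike. Of the features called, 830 were higher in the titled GFP− fraction in both treatments, against 168 expected from independent lists, and 1625 were lower in both, against 192. None was called in opposite directions. Among receptors 341 were higher in both (135 expected) and 193 lower in both (41.9 expected). Across features the differences correlated at r = 0.955 (Spearman 0.698), and across receptors at 0.979. Both comparisons used the same estimate of the spread of each feature, and odor and vehicle pools of the same number correlated. The lists are thus not independent, and the expected counts are only a reference. Features are not independent replicates either, so no p is given.

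**Figure D3:**
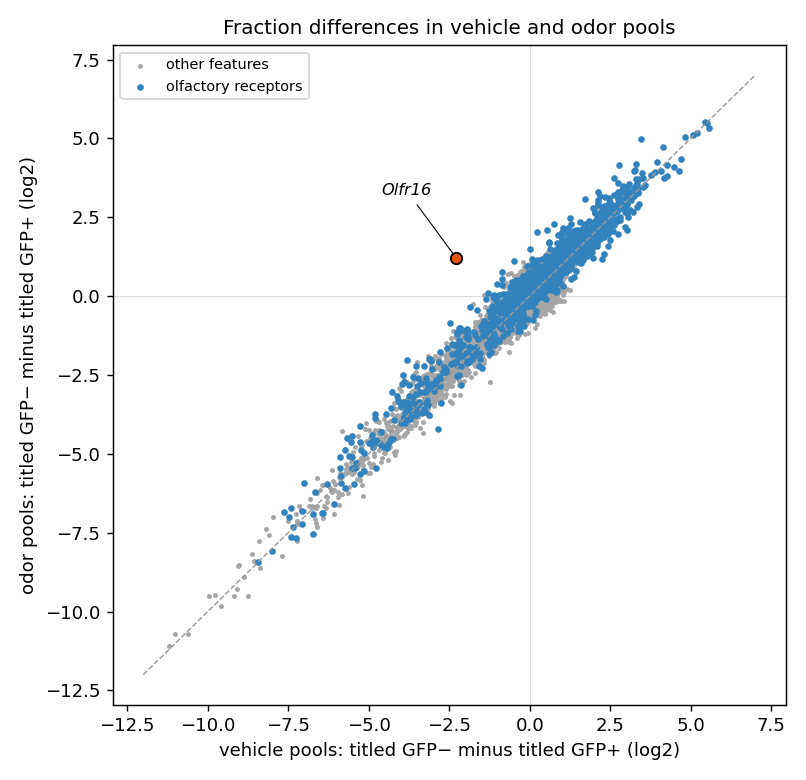
Titled GFP− minus titled GFP+ difference (log2) of each tested feature in odor pools against vehicle pools, with olfactory receptors in blue and the line of equal differences dashed. Receptors follow that line (r = 0.979), and Olfr16 lies apart at −2.28 in vehicle and 1.21 in odor pools.

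The interaction asks whether the odorants changed how a gene was distributed between the fractions, which would single out receptors of responding OSNs. A positive value would mark a response only if the titled GFP− cells are the fluorescent ones. For Olfr16 the fraction difference was 3.48 ± 0.83 log2 units higher in odor than in vehicle pools, the highest among the 1081 receptors. The titled GFP− fraction held more Olfr16 signal in 3 of 4 odor pools (2.75, 2.62, 0.89 and −1.45) and less in all 4 vehicle pools (−2.23, −3.39, −0.32 and −3.17). Over the 2 preset receptors alone it passed by limma (adjusted p = 0.0013, and adjusted p = 0.0089 with the pool as a block). Adjusted over the receptor list alone or over all features it did not pass (0.349 and 0.9997), and an exact permutation test of the pool differences gave p = 0.0571. Olfr2 showed an interaction of −0.13 ± 0.62. Of the other receptors with the smallest p, Olfr1408 had an interaction of 1.62 ± 0.54. Olfr774 was below background on all 4 odor arrays titled GFP+, and Olfr1002 and Olfr127 were above background in the titled GFP+ fraction only, so no interaction is given for them. None of these 4 passed over the receptor list alone.

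Over all features, limma called 0 for the interaction, with 739 at an unadjusted p under 0.05. Without a block, 3.78% of features and 18 of 1081 receptors (1.67%) had such a p, both under the share that chance alone gives. With the pool as a block the counts over all features were 0 and 1051. The non-receptor genes with the smallest p (Dnmt3b, Vmn1r250, Skint5, Hsd17b3 and Rab39) lay below background on all arrays. S100a5 had an interaction of 0.32 ± 0.28, Omp 0.00 ± 0.14, Gap43 0.05 ± 0.43, Kirrel2 −0.28 ± 0.36, Pcp4l1 0.02 ± 0.31, Fos −0.10 ± 0.82 and Egr1 −0.63 ± 0.63. Only ribosomal and oxidative phosphorylation genes were called as lists, with medians of 0.34 and 0.31 (camera adjusted p = 4.2e-10 and 3.0e-07, but adjusted p = 0.959 with an estimated correlation for each, and 0 lists by fry). Both calls were lost without odor replicate 1, at medians of 0.06 and 0.02 (camera adjusted p = 0.339 and 0.972). Camera called further lists upward with 1 pool left out: cell cycle genes without odor replicate 1 (0.71, 6.1e-04) or vehicle replicate 2 (0.61, 0.0475), receptors without odor replicate 2 (0.19, 0.0417) or vehicle replicate 1 (0.23, 0.0070), and Bowman gland markers without vehicle replicate 3 (0.55, 0.0259). In these fits each such list had adjusted p = 0.684 or more with an estimated correlation. The array medians of the negative-control probes had an interaction of −0.38 (exact p = 0.0571). In simulations with independent noise a log2 interaction of 1 was recovered in 40% of features and one of 2 in 90%. The correlated pools and the deviating array of these data were not simulated, so these shares may not hold here.

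**Figure D4:**
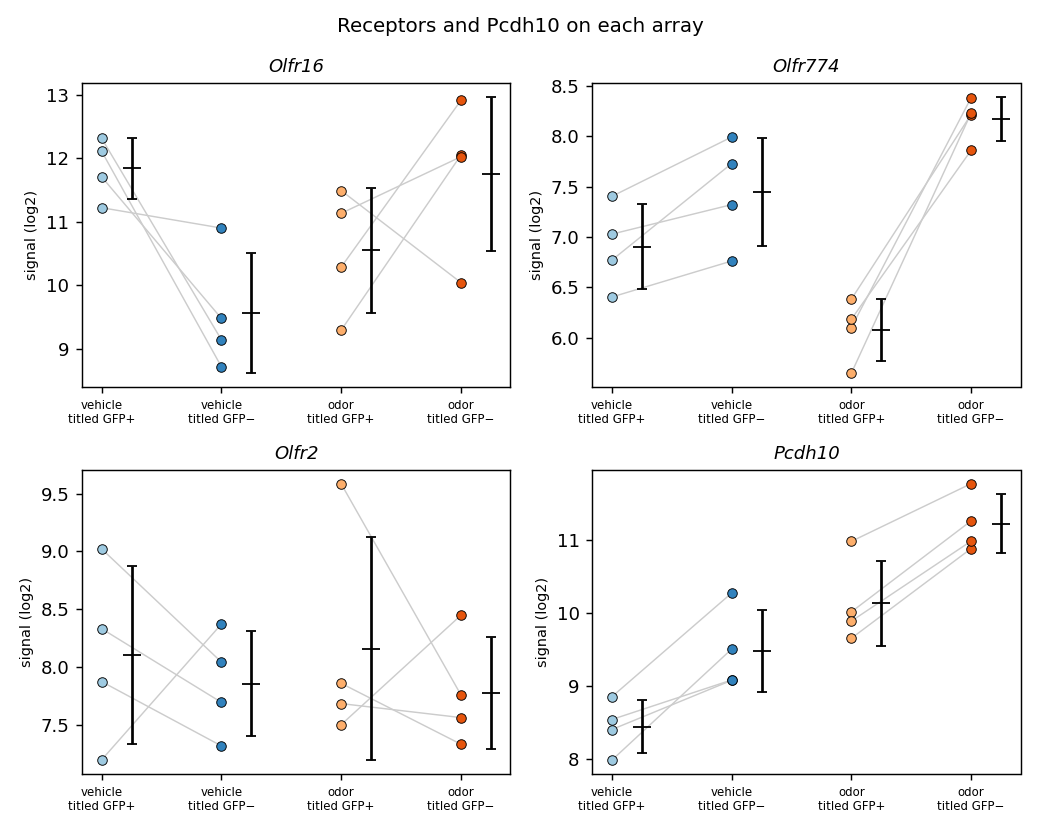
Log2 signals of Olfr16, Olfr774, Olfr2 and Pcdh10 on each array by group, with lines joining the fractions of a pool and bars giving the mean ± SD of 4 arrays. Olfr16 fell from the titled GFP+ to the titled GFP− fraction in all vehicle pools and rose in 3 of 4 odor pools, and Pcdh10 was higher in odor than in vehicle arrays of each fraction.

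Odor against vehicle within the titled GFP− fraction asks which transcript levels differed with the exposure in that fraction. Since the sort follows an activity-driven reporter, the exposure may also change which cells enter a fraction. Changed membership and changed transcription cannot be told apart here. Pcdh10, a protocadherin whose level in OSNs depends on activity, was 1.74 ± 0.31 log2 units higher with odor, with all 4 odor arrays (10.9 to 11.8) above all 4 vehicle arrays (9.08 to 10.3). It missed the threshold over all features (adjusted p = 0.77), passed adjusted over the axon sorting list alone, and passed over all features with the replicate number as a block (adjusted p = 0.0317). Olfr16 was 2.19 ± 0.58 higher, past the threshold over the 2 preset receptors alone (adjusted p = 0.0034) and not over the receptor list alone (0.999). Without the block limma called 0 features, with 805 at an unadjusted p under 0.05. These 805 were 4.11% of features, and 26 of 1081 receptors (2.41%) had such a p, both under the share that chance alone gives. With the block limma called 1 feature, which was Pcdh10, and 1315 had an unadjusted p under 0.05. The next receptors by p were Olfr586 (1.04), Olfr285 (−0.67), Olfr609 (0.88) and Olfr769, not passing, and Olfr769 was above background on 1 of these 8 arrays. Olfr856-ps1, Wnt2b, Prdm16 and Cd207 lay below background in both groups. S100a5 differed by 0.28 ± 0.20, Kirrel2 by 0.53 ± 0.26, Omp by −0.05 ± 0.10, Gap43 by 0.02 ± 0.31, Pcp4l1 by −0.14 ± 0.22, Fos by −0.64 ± 0.58, Egr1 by −0.61 ± 0.45 and Olfr2 by −0.08 ± 0.44, none passing. Camera called no list here (smallest adjusted p = 0.245). With 1 pool left out it called as lower ribosomal (0.0263) and oxidative phosphorylation genes (2.6e-05) without odor replicate 1, the latter also without vehicle replicate 2 (0.0212), and receptors (0.0402) and sustentacular markers (0.0072) without odor replicate 4. In these fits each such list had adjusted p = 0.791 or more with an estimated correlation.

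In the titled GFP+ fraction, odor arrays had lower signals of ribosomal and oxidative phosphorylation genes as lists, with medians of −0.38 and −0.36 (camera adjusted p = 4.2e-14 for each, but adjusted p = 0.578 with an estimated correlation). Without odor replicate 1 these medians were −0.17 and −0.14 (camera adjusted p = 1.8e-04 and 6.7e-04). Of single members 8 of 66 ribosomal genes fell and 1 rose adjusted over the list alone, and 0 of 89 oxidative phosphorylation genes passed by limma. Rpl35, Rps13 and Rpl19 had differences of −0.67 ± 0.18, −0.54 ± 0.14 and −0.49 ± 0.14. Olfactory receptors were lower as a list (median −0.22, camera adjusted p = 0.0020, but adjusted p = 0.775 with an estimated correlation), a median that was −0.03, without a call, without odor replicate 1 (adjusted p = 0.885). The array medians of the negative-control probes were 0.535 higher with odor in this fraction (exact p = 0.0286), against 0.153 in the titled GFP− fraction (exact p = 0.2).

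Pcdh10 was 1.69 ± 0.31 higher with odor here too (adjusted p = 0.30), and adjusted over the axon sorting list alone it and Kirrel2 (0.82 ± 0.26) passed. Lrrc3b (1.07 ± 0.38) and Kirrel2 passed adjusted over the activity-dependent list alone. Wfdc18 (−0.87), Tmem107 (−0.92), Ube2b (−0.61) and Tmem242 (−1.02) had the next smallest p among other genes, and Olfr1109 (−1.32), Olfr1101 (below background on all odor arrays of this fraction), Olfr724 (−0.87), Olfr178 (−0.82) and Olfr723 (−0.73) among receptors. Over all features limma called 0, with 2016 at an unadjusted p under 0.05, or 712 with the negative-control median as a covariate. The 2016 were 10.3% of features, and 55 of 1081 receptors (5.09%) had such a p. With the replicate number as a block the counts over all features were 0 and 2427. Olfr16 was −1.29 ± 0.58, missing the threshold over the 2 preset receptors alone (adjusted p = 0.084), but past it with the block (0.0089), with only the groups compared (0.033), and without odor replicate 4 (−1.60, 0.0112) or vehicle replicate 3 (−1.49, 0.0432). Olfr2 was 0.05 ± 0.44, S100a5 −0.04 ± 0.20, Omp −0.06 ± 0.10, Gap43 −0.03 ± 0.31, Pcp4l1 −0.16 ± 0.22, Fos −0.53 ± 0.58 and Egr1 0.01 ± 0.45. With the block, camera called 8 lists, adding activity-dependent (0.0166) and axon sorting genes (0.0226) as higher, and cell cycle (0.0463), sustentacular (0.0123) and Bowman gland genes (0.0454) as lower. In the unblocked fit these 5 lists had no call, with adjusted p = 0.578, 0.578, 0.840, 0.840 and 0.578 with an estimated correlation, and fry with the block called 0 lists. Without odor replicate 1, camera called 8 lists in the unblocked fit, among them activity-dependent (0.0231) and axon sorting genes (0.0387) upward, and immediate-early (0.0231), cell cycle (4.6e-04), Bowman gland (0.0362) and other leukocyte genes (0.0017) downward. These 6 lists had adjusted p = 0.545 or more with an estimated correlation in that fit. The same directions were called for activity-dependent genes without vehicle replicate 1, axon sorting genes without vehicle replicate 2 or 4, cell cycle and other leukocyte genes without vehicle replicate 2, and Bowman gland genes without odor replicate 2 or vehicle replicate 2 or 3. Sustentacular markers were called lower without vehicle replicate 2 or 3. These calls had adjusted p up to 0.0489, but adjusted p = 0.163 or more with an estimated correlation. Adjusted over their lists alone, 4 ciliated and 2 basal cell markers and 1 Bowman gland marker fell.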

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

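The tests with the negative-control median as a covariate for Olfr16 and of leukocyte markers were chosen after the results were seen, and the limits for reading the signal quality and leukocyte tests were tightened after their values were seen.

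On 3 arrays a value lay far from the other 3 of its group: the negative-control median of odor titled GFP+ replicate 1 (6.06), S100a5 in odor titled GFP− replicate 1 (17.1) and Egr1 in vehicle titled GFP− replicate 3 (8.31). In all, 102 groups of 4 values were examined, and chance alone marks about 1 in 20 such groups.

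Between vehicle and odor pools the fraction difference of Olfr16 differed by 3.48, past the threshold over the 2 preset receptors alone (adjusted p = 0.0013) and not over the receptor list alone (0.349). The medians of ribosomal and oxidative phosphorylation genes differed by 0.339 and 0.305 (camera adjusted p = 4.2e-10 and 3.0e-07, but adjusted p = 0.959 with an estimated correlation for each). Without odor replicate 1 they were 0.06 and 0.02, with no call. The array median of tested features differed by 0.103 (exact p = 0.0286). Outside the genes compared, 254 of 2634 transcript clusters without a gene name passed between the fractions in vehicle pools (84 higher, 170 lower in titled GFP−) and 294 in odor pools (121 higher, 173 lower). Of 5222 negative-control features, 160 passed for odor against vehicle in the titled GFP+ fraction, 159 higher and 1 lower.

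Between the fractions, none of the other 34 splits of 8 arrays called a feature by limma, against 3302 in vehicle and 4338 in odor pools, so 1 of 35 splits, the real one, reached its count in each comparison. Each other split mixes the fractions within its groups. The fraction difference then enters the spread and makes calls unlikely, so these splits say little about chance. Since both fractions come from the same pools, only the 8 splits that part all pairs keep the design, and with 8 splits (highest other 0 in each) the share cannot go under 0.125. For features at an unadjusted p under 0.05, chance could not be excluded. As many came up in 8 of 35 splits for the interaction (739, highest other 1338), in 17 for odor in the titled GFP− fraction (805, highest other 1882) and in 3 for odor in the titled GFP+ fraction (2016, highest other 2833). Among the 8 splits that part all pairs the real one was highest each time (highest others 539, 736 and 1033), and the share there cannot go under 0.125. The other splits keep some pairs together on one side.

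Camera called ribosomal and oxidative phosphorylation genes lower in odor arrays of the titled GFP+ fraction, where negative controls were higher (adjusted p = 4.2e-14 for each list, but adjusted p = 0.578 with an estimated correlation and 0.273 by fry). Without odor replicate 1 the oxidative phosphorylation median was −0.139 and the ribosomal median −0.167, against −0.362 and −0.376 with all arrays. Within groups the oxidative phosphorylation median correlated negatively with the negative-control median over the 8 arrays titled GFP+ (r = −0.546, exact p = 0.0226, adjusted 0.0451; Spearman −0.524, p = 0.0729), but r was 0.330 without the 2 farthest arrays, so signal quality and biology cannot be told apart. A smaller share of leukocytes stays open as well, since neutrophil markers had a median difference of −0.0374 ± 0.0567 and other leukocyte markers of −0.306 ± 0.0753 (SE over member genes, not over arrays). With 4 of 15 other leukocyte markers at a bound, their bounded median was −0.0166, against −0.352 for oxidative phosphorylation genes. The value of −0.306 thus rests in part on members near background, and these markers do not decide the question. An effect of the odorants on these genes was not tested apart from array quality.

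The Olfr16 interaction of 3.48 was 3.29 ± 0.77 with arrays centred on the receptor median and 3.56 ± 1.00 with the negative-control median as a covariate, which argues against a shift of all receptors or of array background as the whole cause. Leaving out 1 pool gave at least 2.97, and 3.18 ± 0.93 at the fewest SE from 0, which argues against a single pool. Cross-hybridization between related receptors was not tested. A response of Olfr16 neurons to the aldehydes stays a hypothesis, and the test passed over the 2 preset receptors but not over all receptors. That reading needs the titled GFP− cells to be the fluorescent ones, as S100a5, the leukocyte markers and the cell type characteristics have it. By the titles the shift would be away from the fluorescent fraction.

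Pcdh10 was higher with odor in both fractions, which came from the same mice and are not independent. In the titled GFP− fraction the difference of 1.74 was 1.81 ± 0.34 with the negative-control median as a covariate, and 1.60 ± 0.35 without the pool that leaves it fewest SE from 0 (vehicle replicate 3), up to 2.00 without another. These values argue against array background and a single pool as the whole cause. Pcdh10 was singled out after its values were seen and passed over all features only with a block by replicate number. The pairing of odor and vehicle pools in that block was inferred. An effect of odor exposure on Pcdh10 thus stays a hypothesis.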

How the results depend on the processing

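The negative-control covariate, the replicate number as a block over all arrays, adjustment over the receptor list alone, list tests without 1 pool (with either correlation), bounded medians and the split by MOR family were chosen after the data were examined. With the pool as a block 3708 features passed between vehicle fractions and 4948 between odor fractions (receptors 660 and 701). Among the genes named in the report and the camera calls of lists, the pool or number block changed no call other than those given there. The cause of the changes below was not tested, except that leaving out pools lowers the number of arrays and a log2 minimum narrows the calls. The class I list by newer receptor symbols was not run. Groups under the 95th percentile of the background probe sets (6.87 to 7.41) on at least 2 of 4 arrays allow only bounds.

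Vehicle fraction calls (3302) were 13985 with arrays centred on the median of tested features, 2150 centred on the receptor median and 1890 with a log2 minimum of 1. Odor fraction calls (4338) were 11192, 2776 and 1924. Without 1 pool they ranged from 2138 to 3867 and from 2689 to 4255. S100a5 in vehicle pools was 0.73 (adjusted p = 0.109) centred on the receptor median. Lists past camera with an estimated correlation were 9 in vehicle and 7 in odor fraction comparisons, and 0 for the interaction and for odor in the titled GFP+ fraction. For the latter pair fry gave 0 lists, also 0 with the replicate block, while centring on the receptor median gave 6 and 10, and 1 for odor in the titled GFP− fraction, each counting the receptor list, whose own level that centring sets. With the replicate block camera gave 8 lists in titled GFP+. Without 1 pool camera called 15 to 17 lists between vehicle and between odor fractions, 1 to 3 for the interaction, 0 to 2 for odor in titled GFP− and 3 to 8 in titled GFP+, and with an estimated correlation 3 to 9, 2 to 8, 0, 0 and 0. Odor against vehicle called 1 feature in titled GFP− with the replicate block, and 1 in each fraction with the number as a block over all arrays (Pcdh10). Olfr16 in titled GFP+ (−1.29) passed over the 2 preset receptors with only the groups compared (0.033) and with the block (0.0089).

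Small values changed sign. After quantile normalization the interaction was −0.0245 for Gap43 and −0.0240 for Pcp4l1, and odor minus vehicle 0.00 for Omp in titled GFP− and 0.067 for Gap43 in titled GFP+. Centred on the median of tested features, Olfr2 in the vehicle fractions was 0.15, the interaction −0.10 for Omp, −0.049 for Gap43 and −0.082 for Pcp4l1, and odor in titled GFP+ 0.069 for S100a5, 0.047 for Omp and 0.075 for Gap43. Centred on the receptor median, Omp was −0.15 in vehicle and −0.35 in odor fractions, Ano2 −0.056, Slc17a6 −0.066 and Adcy3 −0.16 in odor fractions, the interaction −0.19 for Omp, −0.14 for Gap43 and −0.17 for Pcp4l1, odor in titled GFP− 0.0136 for Omp, and in titled GFP+ 0.23 for S100a5, 0.21 for Omp, 0.23 for Gap43 and 0.10 for Pcp4l1. With array weights the interaction was −0.026 for Omp, −0.14 for Pcp4l1, 0.17 for Fos and 0.39 for Olfr2, odor in titled GFP− 0.012 for Olfr2, and in titled GFP+ 0.16 for S100a5, 0.038 for Gap43, 0.016 for Pcp4l1, −0.076 for Egr1 and −0.38 for Olfr2. With the negative-control covariate the interaction was −0.0146 for Omp, −0.14 for Gap43, −0.53 for Pcp4l1 and 0.14 for Olfr2, odor in titled GFP− 0.086 for Pcp4l1, and in titled GFP+ 0.28 for S100a5, 0.24 for Gap43, 0.62 for Pcp4l1, 0.61 for Fos and −0.34 for Olfr2.

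Without 1 pool, Olfr2 in odor fractions ranged from −0.82 to 0.10. Interactions ranged from −0.056 to 0.52 (S100a5), −0.029 to 0.030 (Omp), −0.13 to 0.20 (Gap43), −0.27 to 0.17 (Pcp4l1), −0.24 to 0.062 (Fos) and −0.58 to 0.35 (Olfr2). Odor in titled GFP− ranged from −0.20 to 0.19 (Gap43), −0.24 to 0.038 (Pcp4l1) and −0.30 to 0.090 (Olfr2). Odor in titled GFP+ ranged from −0.17 to 0.19 (S100a5), −0.23 to 0.19 (Gap43), −0.26 to 0.027 (Pcp4l1), −0.21 to 0.30 (Egr1), −0.43 to 0.36 (Olfr2) and −1.60 to −0.87 (Olfr16).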

Other observations

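The tests of pool means, including the activity-dependent list over them and its block, were chosen after the results were seen.

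Receptors of one family tended to share their fraction difference. MOR families, from an older sequence-based naming, held 28.2% of the variance of the vehicle fraction difference over 919 receptors in 120 families of at least 3, against a median of 12.9% and a 95th percentile of 15.7% with family labels permuted (permutation p = 1e-04, the smallest that 10000 permutations allow). In odor pools the share was 29.0%. MOR106 (11 of 13 higher, median 2.91) and MOR179 (5 of 7 higher, 2.64) were higher in the titled GFP− fraction, and MOR225 (7 of 11 lower, −2.96), MOR210 (−4.88) and MOR120 (−6.43) higher in the titled GFP+ fraction. These medians and shares of variance are of the fitted differences, with members below background not taken at their bound, so their size is uncertain. Probes that bind several related receptors were not tested and could add to this share of 28.2%. Neighbouring receptor genes of different families correlated at r = 0.0703 over 424 pairs (permutation p = 0.07) and 0.0583 in odor pools, which leaves an effect of genomic position open.

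With the fractions of each pool averaged, limma called 0 features for odor against vehicle, with 1430 at an unadjusted p under 0.05, and 1 with the replicate number as a block, Pcdh10 (1.71, adjusted p = 0.0034). The activity-dependent OSN genes had a median of 0.123 (camera p = 0.0148, and p = 0.0460 with an estimated correlation). With the replicate number as a block these were p = 0.0023, and p = 0.0519 with an estimated correlation. Of the 7 genes, Kirrel2 differed by 0.67, Lrrc3b by 0.89, Rasgrp4 by 0.38, S100a5 by 0.12, Plcxd3 by 0.12, Pcp4l1 by −0.15 and Slc17a6 by −0.069. Over the list alone limma passed none of them (adjusted p of 0.0847 to 0.491), but with the block it passed the first 3 (adjusted p = 0.0012, 0.0052 and 0.0205). A rise of Kirrel2, Lrrc3b and Rasgrp4 with odorants is a hypothesis found and tested on the same 8 pools.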
